A study of Mus musculus with 11 samples.

How the data were processed

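Total RNA of whole mouse liver lysates was labelled with biotin and hybridised to 1-colour Illumina bead arrays, 1 sample to an array, per the labels. The 11 samples were grouped by their source labels into vehicle for 14 d (n = 3), Sorafenib at 60 mg/kg for 14 d (n = 4) and Sorafenib at 60 mg/kg for 83 d (n = 4). The labels also give the chip and the position of each array. The shared chip held 8 arrays, namely the 3 vehicle arrays, all 4 long-term arrays and 14 d replicate 4, and the second chip held 14 d replicates 1 to 3.

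The deposited values were 1 intensity per probe and array for 26512 probes, processed by the authors and on a linear scale, as judged from the values. The software, background correction and normalization behind these intensities were not given in the sources used here. The lowest intensity was 74.1 and the array medians were 98.7 to 99.9, so a background had not been subtracted to 0. Sorted intensities of the arrays deviated from their mean over arrays by a median of 0.419%, with a 99th percentile of 1.90% and a largest deviation of 6.80%, so the arrays had been brought close to a single distribution before they were deposited. Detection calls were not used here. The background that remained in the intensities makes fold changes of dim probes smaller than the changes in transcript level.

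An offset of 16 was added, the log2 was taken and the arrays were quantile normalized, because they did not share 1 distribution exactly. The normalized log2 levels of the probes had a median of 6.84 and quartiles of 6.74 and 7.61, so that most probes lay close to the background. All fold changes are on the log2(intensity + 16) scale. Group means were compared with limma 3.58.1 in R 4.3.3, with lmFit on all 11 arrays in 3 groups and eBayes with an intensity trend, so that the groups shared 1 estimate of the spread. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the 26512 probes of each comparison, and the threshold was an adjusted p of 0.05. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Errors are the SD over arrays or the SE of the fit, as stated at each value.

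The plan, made before the data were examined, was to test 1 probe per gene symbol and 34 gene lists covering cell types and pathways. No table pairing these probes with genes was used here, so each probe was tested on its own, and the gene lists, the tests of lists and the genes that were to be named in every case were not analysed here. The rule for naming took the 10 probes with the largest rise and the 10 with the largest fall among those past the threshold whose arrays in both groups did not overlap. Because identifiers without gene names can hardly be interpreted, only the first 2 in each direction are printed.

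The fit was tested on simulated data with the real probes, in which 200 brighter probes were changed by known amounts. For 14 d against vehicle it recovered 73.1% of changes of 0.5 on the log2 scale, 97.0% of changes of 1 and 100% of changes of 2, with 5 false calls among 185. For long-term against vehicle the shares were 59.7%, 92.5% and 98.5%, with 7 false calls among 174. For long-term against 14 d they were 71.6%, 97.0% and 100%, with 5 false calls among 184. Each comparison had a single draw, with 66 or 67 probes of each size. The shares therefore do not show that the comparisons differ in power. The simulated noise was independent between probes and between arrays and held no shift between chips. These shares therefore do not cover errors that come from the chip.

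The chip was entered as a fixed term and as a random block, and each comparison was repeated on the shared chip alone. The chip term passed the threshold for 1 probe, and 1726 probes reached an unadjusted p under 0.05 where 1325.6 would by chance. This term rests on the 14 d arrays alone, those of the second chip against the only 14 d array of the shared chip. It can therefore find only large shifts, and it cannot tell the chip from a difference of that array itself. As a random block the correlation of arrays within a chip was 0.0170. Position on the chip followed the groups, with vehicle arrays at F to H, long-term arrays at B to E and 14 d arrays at A on the shared chip and F to H on the second. Other alternatives were no quantile normalization, centring on the median, only the brighter probes, only the groups compared, no intensity trend, arrayWeights, offsets of 1 and 50, the replicate number as a block and leaving out each array in turn. Normexp background correction and leaving out a run of dim probes were added after the data were seen. Overlap between comparisons against the same vehicle arrays was set beside 100 simulations of unchanged groups. Signs and fold ratios among long-term calls were set beside 100 simulations without a 14 d effect, drawn from the group means and the residual SD of each probe. Opposite calls were set beside 100 simulations without a change between the times, drawn in the same way.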

Results

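Liver RNA was profiled in iAST mice, a C57BL6n line whose samples were labelled tumour liver, after oral Sorafenib or vehicle. Sorafenib is a multikinase inhibitor that blocks RAF kinases and the receptors for VEGF and PDGF, and it is used against hepatocellular carcinoma. Total RNA of whole liver lysates was measured on 11 arrays in 3 groups: 3 arrays of livers given vehicle for 14 d, 4 of livers given Sorafenib at 60 mg/kg for 14 d, and 4 of livers given the same dose for 83 d, called long-term here. Each array gave an intensity for the same 26512 probes, and the median intensity of an array lay between 98.7 and 99.9. Probes are given by their Illumina identifiers because no table pairing them with genes was used here, so the text describes changed transcripts without naming their genes. The number of arrays limits the precision, and the labels do not say that each array came from a different mouse, so that p-values measure the spread between these samples, which may be technical.

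The vehicle and long-term livers separated, whereas on the first principal component the 14 d liver on the shared chip lay close to vehicle. Over the 13256 brighter probes, the first principal component held 34.7% of the variance and placed the vehicle livers between -21.1 and -11.5 and the long-term livers between 11.6 and 19.2. Livers treated for 14 d lay between them: replicates 1 to 3 at -2.95 to 0.32 and replicate 4 at -10.9, just past the nearest vehicle liver. The second component, with 17.9%, set 14 d replicates 1 to 3, at -14.7 to -11.0, apart from 14 d replicate 4, at -2.58. These 3 arrays were on a second chip, whereas 14 d replicate 4 shared its chip with all vehicle and all long-term arrays. Pairs of livers of the same group differed with a median SD of the log2 difference of 0.24 for vehicle, 0.23 for 14 d and 0.22 for long-term. Pairs across groups had higher medians, of 0.28 for vehicle and 14 d, 0.29 for 14 d and long-term, and 0.34 for vehicle and long-term. The 3 pairs of vehicle and 14 d livers on the same chip, at 0.24 to 0.28, lay within the range of vehicle pairs, 0.22 to 0.30. By this measure 14 d replicate 4 was about as close to the other 14 d livers, at 0.243 to 0.245, despite the different chip.

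**Figure D1:**
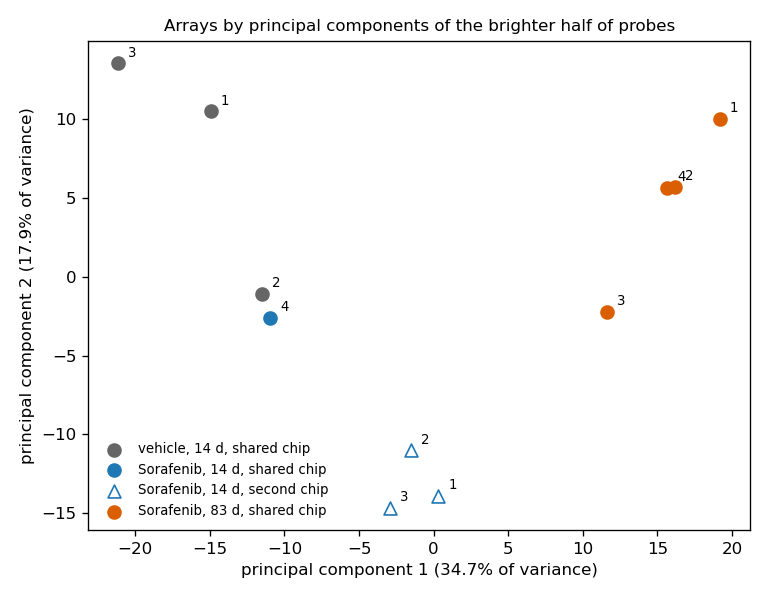
Principal components of the log2 intensities of the 13256 brighter probes, with the first component (34.7% of the variance) on the horizontal and the second (17.9%) on the vertical axis; each point is an array, numbered by replicate and marked by group and chip. The long-term arrays lie at 11.6 to 19.2 on the first component and the vehicle arrays at -21.1 to -11.5, and 14 d replicate 4, the 14 d array on the shared chip, lies apart from the other 14 d arrays.

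The comparison of 14 d of Sorafenib with vehicle asks which liver transcripts differed after short exposure. Lower levels predominated: 309 probes passed the threshold (limma, adjusted p under 0.05), 235 of them lower and 74 higher with Sorafenib. The changes were mostly moderate, with a median log2 fold change of -0.63 among the lower and 0.72 among the higher probes, and 38 probes were at least 2-fold lower and 19 at least 2-fold higher. Of the 309, 308 were among the 13256 brighter probes. In 297 of the 309 the levels of the 4 treated livers and the 3 vehicle livers did not overlap. Over all probes, 9.23% showed such separation, against 5.71% by chance.

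Probe ILMN_1257574 fell from a log2 level of 9.02 ± 0.40 (SD, n = 3) with vehicle to 7.26 ± 0.08 (SD, n = 4) at 14 d. Its log2 fold change was -1.76 ± 0.13 (SE), with a limma adjusted p of 3.57e-07, and it was likewise low in the long-term livers, at 7.02 ± 0.07 (SD, n = 4). ILMN_2710905 fell by 1.76 ± 0.37 (SE) on the log2 scale, with a limma adjusted p of 0.0171, from 11.38 ± 0.62 to 9.62 ± 0.32. Its call was lost without vehicle replicate 1 (adjusted p = 0.134), vehicle replicate 2 (0.0677) or 14 d replicate 3 (0.0715), and without an intensity trend in the variance (0.161). Among the higher probes, ILMN_1256775 rose 4.55-fold, by 2.19 ± 0.33 (SE) on the log2 scale with a limma adjusted p of 0.00115, from 7.45 ± 0.20 to 9.64 ± 0.70. ILMN_1226935 rose 3.32-fold, by 1.73 ± 0.22 (SE) with an adjusted p of 3.28e-04, from 10.46 ± 0.57 to 12.20 ± 0.42. Both of these were at a similar or higher level in the long-term livers, at 9.69 ± 0.73 and 12.69 ± 0.17. After a background correction the log2 fold changes of ILMN_1257574 and ILMN_1256775 were -2.57 and 2.91.

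The number of calls at 14 d depended on how the chip was treated. With the chip as a term in the model, which rests the comparison on 14 d replicate 4, 6 probes passed (1 higher and 5 lower), 4 of them among the 309. Within the shared chip alone, where 1 treated liver was set against 3 vehicle livers, 2 probes passed, both lower, and 1 was among the 309. With the chip as a random block, whose correlation was estimated at 0.0170 from the 2 chips, 292 probes passed, all among the 309. At an unadjusted p under 0.05 the counts were 2588 without the chip term, 1554 with it and 1457 within the shared chip. The median size of the 309 was 0.53 on the log2 scale with the chip term against 0.65 without it, while the median standard error over all probes rose from 0.05 to 0.08. Replicate 4 was among the arrays by which the 309 were chosen, so their size and direction in it are no independent check. ILMN_1257574 was past the threshold with the chip term (-1.77, adjusted p = 5.32e-04) and within the shared chip (adjusted p = 0.00646), where the 1 treated array had no replicate and was assumed to vary like the arrays of the other groups. The calls of ILMN_1256775 (1.57, adjusted p = 0.460), ILMN_1226935 (1.21, adjusted p = 0.262) and ILMN_2710905 (-1.71, adjusted p = 0.605) ended with the chip term, and within the shared chip their adjusted p were 0.471, 0.376 and 0.736. Without vehicle replicate 1, 200 probes passed, 26 higher and 174 lower. Without 14 d replicate 4, 423 passed, 131 higher and 292 lower.

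**Figure D2:**
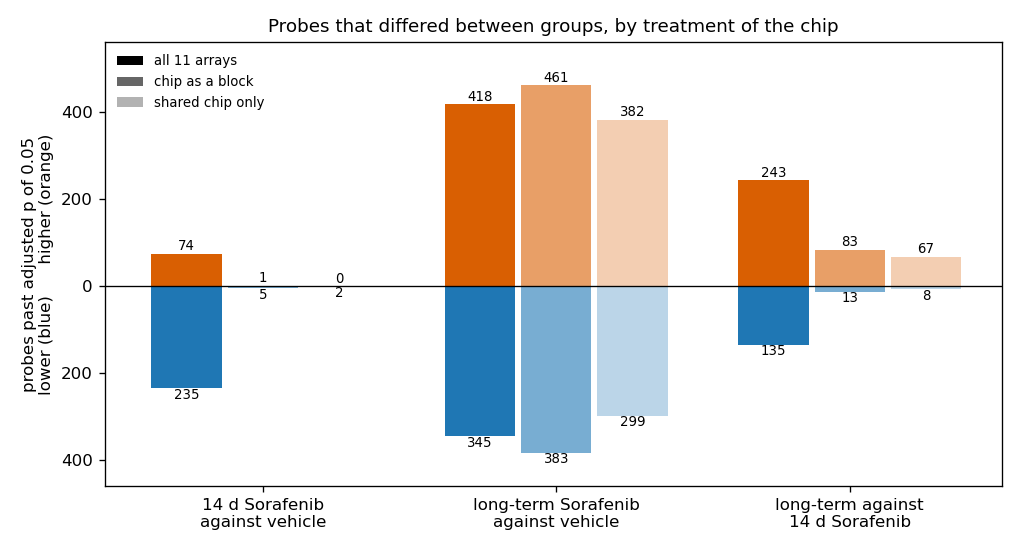
Number of probes past an adjusted p of 0.05 in each comparison, with bars above 0 for higher and below 0 for lower probes, for all arrays, with the chip as a term, and within the shared chip. The count for 14 d against vehicle falls from 309 to 6 and 2, that for long-term against 14 d from 378 to 96 and 75, and that for long-term against vehicle is 763, 844 and 681.

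The comparison of long-term Sorafenib with vehicle asks which transcripts differed after 83 d of drug. More probes passed than at 14 d, and their directions were more even: 763 probes, 418 higher and 345 lower. The difference in count and in direction was not itself tested. Among them 108 were at least 2-fold higher and 53 at least 2-fold lower, with median log2 fold changes of 0.70 and -0.57. The groups were fully apart in 730 of the 763, and over all probes in 12.2% against 5.71% by chance. All arrays of this comparison were on the shared chip, so the chip did not differ between its groups. Within that chip 681 probes passed (382 higher and 299 lower), 625 of them among the 763, and with the chip as a term 844 passed, 754 of them shared.

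The strongest rises were large. ILMN_2612117 rose 17.8-fold, by 4.15 ± 0.25 (SE) on the log2 scale with a limma adjusted p of 9.26e-09, from 7.27 ± 0.34 (SD, n = 3) with vehicle to 11.42 ± 0.62 (SD, n = 4). Each of the 4 long-term livers lay at or above 10.90, and none of the other 7 livers exceeded 7.98. ILMN_1214531 rose 15.3-fold, by 3.94 ± 0.35 (SE) with an adjusted p of 1.73e-06, from 7.48 ± 0.54 to 11.42 ± 0.63. Both started near the level at which most probes lie, so their folds are understated by the background left in the intensities, and after a background correction they were 5.21 and 4.83 on the log2 scale. ILMN_2896768 fell by 2.38 ± 0.37 (SE), with a limma adjusted p of 7.77e-04, from 10.59 ± 1.25 to 8.21 ± 0.44, and without vehicle replicate 3 its log2 fold change was -1.66. ILMN_3118584 fell by 2.12 ± 0.36 (SE), with a limma adjusted p of 0.00161, from 11.08 ± 0.84 to 8.96 ± 0.61. At 14 d the latter was at 8.88 to 9.18 in replicates 1 to 3. In 14 d replicate 4 it was at 10.32, the level of vehicle replicate 2. Its log2 fold change of -1.75 at 14 d (limma adjusted p = 0.0145) rested on replicates 1 to 3, the arrays of the second chip. With the chip as a term it was -0.76 (adjusted p = 0.918).

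No vehicle arrays at 83 d were analysed here, so this comparison differs in time as well as in drug. The count was 480 without vehicle replicate 1 and 494 without vehicle replicate 3.

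The comparison of long-term with 14 d Sorafenib asks which transcripts differed between short and long exposure. With no vehicle arrays at 83 d, it tests the levels of the treated livers, and the length of exposure goes together with time. Higher levels predominated: 378 probes passed, 243 higher and 135 lower in the long-term livers. Of these 63 were at least 2-fold higher and 13 at least 2-fold lower, with median log2 fold changes of 0.68 and -0.61. The groups were fully apart in 343 of the 378, and over all probes in 6.69% against 2.86% by chance. ILMN_2612117 and ILMN_1214531, the strongest rises against vehicle, were also higher in the long-term than in the 14 d livers. ILMN_2612117 was 3.73 ± 0.24 (SE) higher on the log2 scale than at 14 d (13.3-fold, limma adjusted p = 1.95e-08), and ILMN_1214531 3.30 ± 0.32 higher (9.88-fold, adjusted p = 5.81e-06). At 14 d they differed from vehicle by 0.42 (adjusted p = 0.657) and 0.64 (adjusted p = 0.598), which did not pass. After a background correction the difference between the times for ILMN_2612117 was 4.43.

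ILMN_2958159 rose by 0.65 at 14 d (adjusted p = 0.00859), from 11.93 ± 0.24 to 12.58 ± 0.11, a call that ended with the chip as a term (0.81, adjusted p = 0.174). It was 11.08 ± 0.13 in the long-term livers, below vehicle by a log2 fold change of -0.85 (adjusted p = 3.73e-04). The difference between the treated groups was -1.50 ± 0.11 (SE), with a limma adjusted p of 2.47e-07. ILMN_2600744 fell by 2.47 ± 0.51 (SE) between 14 d and long-term, with an adjusted p of 0.0152, from 11.33 ± 0.68 to 8.86 ± 0.95. The vehicle livers were widely spread for this probe, at 9.39 ± 1.68. Its call was lost without 14 d replicate 1 (adjusted p = 0.0505), 14 d replicate 3 (0.0689) or long-term replicate 4 (0.0618), and without the intensity trend (0.137).

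With the chip as a random block 341 probes passed, all among the 378. With the chip as a fixed term 96 probes passed (83 higher and 13 lower), 79 of them among the 378, and within the shared chip, against 1 liver treated for 14 d, 75 passed (67 higher and 8 lower), 66 of them shared. The median size of the 378 was 0.64 both with and without the chip term, in probes chosen with 14 d replicate 4 among the arrays. With that term ILMN_2612117 (3.60, adjusted p = 1.00e-04), ILMN_1214531 (4.04, adjusted p = 3.28e-04) and ILMN_2958159 (-1.66, adjusted p = 1.00e-04) kept their calls, and ILMN_2600744 (-2.04, adjusted p = 0.455) did not. Within the shared chip the adjusted p of these 4 were 4.69e-04, 4.69e-04, 9.56e-04 and 0.519. The count was 194 (141 higher and 53 lower) without long-term replicate 1 and 228 (161 higher and 67 lower) without long-term replicate 2. Without 14 d replicate 3 it was 249 (169 higher and 80 lower).

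**Figure D3:**
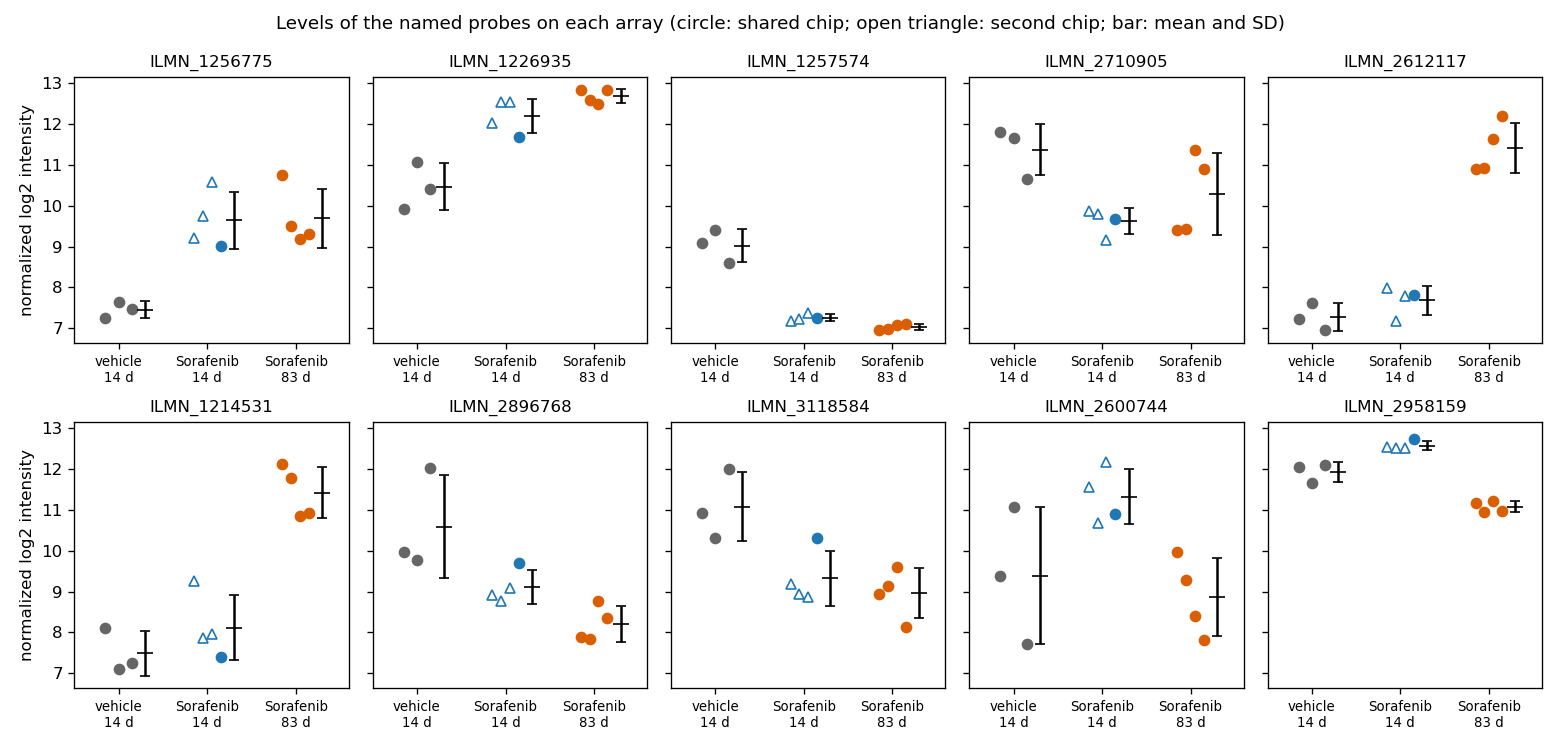
Normalized log2 intensity of the named probes in each array, by group, with points for arrays and a line and bar for the group mean and SD. ILMN_2612117 and ILMN_1214531 are high in the 4 long-term arrays, with means of 11.42 and 11.42 against 7.27 and 7.48 with vehicle, and ILMN_1257574 is high only in the 3 vehicle arrays.

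Across the 3 comparisons 1040 probes passed at least once. Of the 309 probes called at 14 d, 159 were also called in the same direction in the long-term livers, 30 higher and 129 lower, and 1 in the opposite direction. Independent lists of these lengths would share 1.17 higher and 3.06 lower probes. In 100 simulations of 3 unchanged groups with 1 vehicle group in common, lists of equal length ranked by p shared 83 to 115 probes in the same direction, against the 159. The 3 vehicle arrays cannot be split so that each part keeps 2, so the overlap of calls was not measured without shared vehicle arrays. A shift was measured in 300 probes chosen between long-term and vehicle, against a vehicle array left out of the choice. In the long-term direction, the mean of the 14 d livers on the second chip shifted by 0.24 to 0.43 on the log2 scale. The shift of 14 d replicate 4 was 0.15 to 0.30 against vehicle replicates 1 and 3, and -0.02 to 0.01 against vehicle replicate 2. The simulations allow for the sharing only where no group changed. The fold changes of both comparisons had a covariance across probes of 0.0187, against 0.00514 in the simulations, a difference of 0.0135. Their correlation across probes, which are not independent replicates, was 0.619 against 0.539 to 0.602 in the simulations. The same sign was found in 69.4% of probes, equal to the simulated mean of 69.4%.

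Of the 763 long-term calls, 712 (93.3%) had a 14 d fold change of the same sign, 383 of the 418 higher and 329 of the 345 lower. The shared vehicle arrays favour this: in 100 simulations with the observed long-term levels and no 14 d effect, 67.9% to 73.1% of long-term calls had the same sign. The median ratio of the 14 d to the long-term fold change was 0.451, against 0.115 to 0.149 in these simulations, which held no effect of the chip. They took the measured group means as true and added noise to them again, so both simulated ranges may be too low. A total of 603 long-term calls were not called at 14 d, and for 209 of these the long-term level also differed from the 14 d level in the same direction. For 394 neither the 14 d change nor the difference between the times passed. Of the 309 probes called at 14 d, 37 were called the opposite way between 14 d and long-term, and 34 of these were not called in the long-term livers against vehicle. Both comparisons used the same 4 arrays of 14 d with opposite sign, which favours opposite calls. A shift of the 3 arrays on the second chip would give opposite calls too. In 100 simulations with the observed 14 d levels and no change between the times, 0 probes were called opposite ways, against the 37. They gave 939 to 1236 calls at 14 d, against 309, so they did not match the data. They also held no true difference between the times, so they do not show what sharing adds where some exist.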

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

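The tests of the chip and of other splits of the arrays were chosen before their results were seen. With 35 splits, 1 of 35 is the smallest share that could be found. The splits also treat the arrays as separate samples that could be exchanged, which neither the labels nor the chips ensure. The tests of position and of time were chosen after.

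Results were picked out here where the long-term and the 14 d livers, both set against the same vehicle livers of 14 d, differed by a test of the difference itself. This held for 378 probes. Among the named probes the long-term level exceeded the 14 d level by 3.73 on the log2 scale for ILMN_2612117 and by 3.30 for ILMN_1214531. It lay below it by a difference of -2.47 for ILMN_2600744 and of -1.50 for ILMN_2958159. None of 22 sets of values from groups of 4 arrays (the named probes in each treated group and the array medians) passed Dixon's test for a single outlying array, which at this size finds only very wide gaps: ILMN_3118584, at 10.32 in 14 d replicate 4 and 8.88 to 9.18 in the other 14 d livers, did not pass it.

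The difference between long-term and 14 d livers was weighed against chance and the second chip. In only 1 of the 35 splits of the 8 arrays, the real one, did as many probes pass, with 378 against 8 in the highest other, which argues against chance. If the second chip were the whole cause, long-term livers would differ little from 14 d replicate 4 on their own chip. In 300 probes selected without the arrays compared, they differed from it by 0.47 on the log2 scale (0.38 to 0.58), which was 96.4% of their difference from the 14 d livers on the second chip. This passed the bound of 50% set in advance against the chip, but that bound was wrong in resting on 1 liver of 14 d, which can differ from the long-term livers for reasons of its own, so a part played by the chip stays open, and so do the length of exposure and, untested, the time and age that go with it.

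The 14 d response to Sorafenib is the pattern most tied to the chip. The real split, with 309 probes, was the only 1 of 35 to give as many, which argues against chance. The highest other split gave 178 and followed the chip, with the 14 d liver of the shared chip placed among the vehicle livers, whereas the chip as a term left 6 probes and the shared chip alone 2. In 300 probes selected without the arrays compared, that liver shifted from vehicle by 0.29 on the log2 scale (0.19 to 0.36) in the direction of the others, which was 63.8% of their 0.46 (0.40 to 0.52). That is above the bound of 50% set in advance, but it too rests on 1 liver, so how much of the response the second chip may account for stays open, beside an effect of the drug.

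The long-term response was weighed against chance, position and time. The real split, with 763 probes, was the only 1 of 35 to give as many, and the highest other, 238, placed long-term replicate 3 among the vehicle livers, which argues against chance and points to that liver as the least distinct of its group. Long-term arrays lay at positions B to E and vehicle arrays at F to H. The 14 d array at A, farther along the chip, shifted by a median of 28.0% of the long-term shift. It shifted by 23.6% to 34.4% against held-out vehicle replicates 1 and 3, and by -2.56% to 1.71% against vehicle replicate 2. A trend along the chip would need about the whole of the long-term shift. The 3 arrays of 14 d at F to H, the positions of the vehicle arrays, shifted by 48.8% (37.3% to 54.1%). Position alone would give none there. The values of the array at A rest on 1 array and those of the arrays at F to H on another chip, so neither decides about position. With 0 vehicle arrays at 83 d, the drug cannot be told apart from the time, age or tumour growth that passed in the livers.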

How the results depend on the processing

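Normexp background correction and leaving out the run of dim probes were tried only after the data were seen. The count for long-term against vehicle stayed within 1.5 times 763 under all settings but those that left out vehicle replicate 1 or 3. Counts for 14 d against vehicle were 6 with the chip as a fixed block, 2 on the shared chip alone, 7 with the replicate block and the chip together (5 higher and 2 lower, where the 309 were mostly lower), and 187 without the intensity trend, against 309. For long-term against 14 d they were 96, 75 and 62 under the first 3 of these, against 378. The chip settings rest the 14 d group on fewer arrays, and the cause of the loss without the trend was not tested. Leaving out each array in turn gave 200 to 423 probes for 14 d against vehicle, 480 to 847 for long-term against vehicle and 194 to 473 for long-term against 14 d. The lowest were 200 and 480 without vehicle replicate 1 and 194 without long-term replicate 1, and counts also moved by over 1.5 times without vehicle replicate 3 (494), long-term replicate 2 (228) and 14 d replicate 3 (249). The total counts of all other settings stayed within that bound. No direction of a named probe turned in 312 checks, of which 292 kept the call and 20 lost it: 7 each for ILMN_2600744 and ILMN_2710905, 3 each for ILMN_1226935 and ILMN_1256775. Many checks could not turn a direction, since leaving out an array of a group not compared, for example, left the fold change unchanged. Replicate numbers did not pair the arrays: 1 of 10 same-number pairs correlated above 0.1, and 1 array correlated best with its own number. The replicate block gave 340, 768 and 359 probes, 278, 657 and 309 of them shared with the fit without it. Tests that need gene names (the mean of the probes of a gene, gene lists with camera at a preset or an estimated correlation, fry) were not run. Signal over background is a limit for most probes, since levels had a median of 6.84. Normexp raised the log2 fold changes of ILMN_1256775 at 14 d to 2.91 and of ILMN_2612117 between the times to 4.43. It lowered that of ILMN_1257574 at 14 d to -2.57. The counts with normexp were 341 for 14 d against vehicle, 750 for long-term against vehicle and 398 for long-term against 14 d.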

Other observations

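The test and the features below were chosen after the data were seen. A small set of transcripts was present at 2 separate levels across the 11 livers. In 14 probes a gap of over 1 on the log2 scale, wider than the range of levels on either side of it, parted high from low arrays. Gaps that set only 1 array apart were not counted. In 5 of these the high arrays were exactly the 4 long-term livers, ILMN_2612117 among them, and in 1, ILMN_1257574, they were the 3 vehicle livers. In 3 others the high arrays were long-term replicates 1, 2 and 4 but not 3.

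Another pair split the livers across the groups. ILMN_1241001 was at 6.62 to 6.76 in vehicle replicate 1, 14 d replicate 1 and all 4 long-term livers, and at 8.43 to 8.93 in the other 5. ILMN_2899599 split the same livers, at 7.57 to 8.02 and 9.29 to 10.45. Between long-term and 14 d neither passed the test (limma adjusted p = 0.0787 and 0.146).

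In each group 1 liver correlated least with the rest, as 1 must in any group. The mean correlation of long-term replicate 3 with the other long-term livers, across the brighter probes after removing each probe's mean, was 0.212, against 0.358 to 0.460 for the others. For 14 d replicate 4, on which the 14 d values with a chip term rest, it was lower, at 0.0345 against 0.178 to 0.201 for the other 14 d livers. Those others were all on the second chip, so the chip and this liver itself cannot be told apart. Among the vehicle livers replicate 2 was lowest, at 0.214 against 0.321 and 0.414, so a low value was not particular to treated livers. Among the 763 probes called in the long-term livers long-term replicate 3 stood apart from the rest of its group in 24, or 3.15%, against 1.25% by chance and 3 to 6 probes for each of the others. Chance sets an array apart in about 1 of 20 groups. The 14 d liver on the shared chip stood apart in 9 of 309 probes called at 14 d, or 2.91%.

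In the order of their identifiers, 798 consecutive probes all lay below the 75th percentile of level, where the next longest such run had 52 and the longest in 1000 shuffled orders 57. Their levels were 6.65 to 7.09, and 0 of them passed the threshold in any comparison by limma. At an unadjusted p under 0.05 in at least 1 comparison there were 93, for which no number by chance was worked out. At the share of the 16386 other probes up to the highest level of the run, 4.53 would have passed the threshold, so that the absence of calls says little about probes this dim. A candidate explanation is that these probes have no target in the samples, such as negative controls, but neither the run of 798, from which the idea came, nor the absence of calls decides it.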
